A study of Danio rerio with 12 samples.

How the data were processed

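RNA was measured in cardiac tissue of zebrafish (Danio rerio) from a line that carries ATF3 under the myl7 promoter, which drives expression in heart muscle cells, and from wild-type siblings. Tissue was taken at 4 and 12 months post-fertilization (mpf), with 3 biological replicates for each genotype and age, 12 libraries in all. Libraries were made with the QuantSeq 3' FWD kit, in which oligo-dT priming places reads near the 3' end of a transcript and on its sense strand, and were sequenced single-end, per the labels' protocols. No molecular identifiers are named there, so floors and intervals cover counting error only. Groups were taken from the titles and the genotype and age labels, and each of the 12 value columns matched 1 library, with 0 columns left over.

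The deposited values were FPKM (fragments per kilobase of transcript, scaled per library), per the name of the table. The submitters' processing notes name Trim Galore, STAR, RSEM and DESeq2 and the genome build GRCz11. Their versions, the annotation release and the strand setting of the counting are not given in the sources used here. The table had 32520 genes with coordinates and biotypes, of which 400 held values in all 12 libraries. The other 32120 genes, atf3 and myl7 among them, were not analysed here. Of the 400 genes, 333 were protein-coding, 42 antisense, 10 processed transcripts, 6 rRNA, 6 lincRNA, 2 mitochondrial rRNA and 1 a polymorphic pseudogene. A name was blank for 7 of them, and 366 of the 400 identifiers were found in the gene name table.

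Reads were recovered from the FPKM values to show the depth behind each one. A factor per library was solved from 10 mitochondrial genes, on which it had a relative spread of at most 4.6e-15, and a length was solved for each gene. All 400 genes gave whole reads in every library within 0.0001 reads, and all 400 recovered lengths were no longer than the gene's span, with a median of 2885 bases. The recovered reads in the 400 genes ranged from 133852 to 1092280 per library. That total is not the library's depth, since it covers only these genes. In the 6 libraries of 4 mpf it was 1.241 to 1.974 times the factor recovered for the library, so the values were not scaled to all mapped fragments. Over the 129 genes above 0 throughout, the median ratio of a library's values to their geometric mean was 0.967 to 1.132, and the scaling used is not given in the sources used here. A value of 0 was given a floor of 3 reads per library, which at the median length corresponds to 2.14 FPKM. A fold against a group listed at 0 in all 3 libraries was computed against that floor as a bound. The bound counts each read as a separate molecule, and is too high where reads are copies.

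Values were used with no further scaling and transformed as log2(FPKM + 1). Genes with at least 1 FPKM in at least 3 libraries were tested, a filter that all 400 passed. A model with 1 mean for each of the 4 groups was fitted to all 12 libraries with limma 3.58.1 in R 4.3.3, with eBayes set to trend and robust, so that the 4 groups shared 1 estimate of the spread per gene. Transgenic and wild-type hearts were compared at 4 mpf, at 12 mpf and over both ages. The difference between those effects (interaction) and the change from 4 to 12 mpf within each genotype were also tested. All tests were two-sided, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The effects at both ages were correlated across genes, which are not independent replicates. Measures of single libraries were compared with exact permutation tests, two-sided, 35 in the family. For 3 libraries against 3 the smallest p such a test allows is 0.1. Opposite-strand overlaps were counted from the table's coordinates and compared with Fisher's exact test. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for these steps.

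The tests, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. By that rule atf3 and myl7 come first. For each comparison of genotypes at 1 age, up to 10 rises and 10 falls with the largest change followed, among genes under the threshold whose 3 transgenic libraries all lay on one side of the 3 wild-type libraries. Up to 5 rises and 5 falls were named for the other comparisons, without the condition on separate groups for the interaction and with that condition met at each age for the comparison over both ages. Up to 4 passing members of each list were added at each age. Where fewer than 10 genes passed between genotypes at 1 age, the 10 with the smallest unadjusted p were named. Genes without a proper symbol were counted but not named, except where the text says that they were chosen after their values were seen. The prefixes CT, AL, KN and NC_ of clone and contig names were added to the written list of such names after the table was seen, which affects the rRNA genes of the CT583728 clone.

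There were 34 gene lists with 958 matched members, of which 28 members in 10 lists had values. These were cell cycle and DNA replication, cytosolic ribosomal proteins, erythrocytes, integrated stress response, interferon response and antigen presentation, liver, mitochondrially encoded, nuclear encoded oxidative phosphorylation, proteasome, and surface epithelium and gill. The other lists, which covered the sarcomere, ion channels, calcium handling and cardiac stress among others, were not analysed here. Lists with at least 5 members were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Only the mitochondrially encoded list was that large. The p of camera was adjusted over the lists tested in a comparison, which with 1 list leaves it unchanged. Members were also adjusted over their list alone, which for lists with 1 measured member leaves p unchanged, so a choice made after the results were seen was to judge such members over all genes only.

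The alternatives set in advance were other pseudocounts, no filter and a mean of at least 5 FPKM, median-of-ratios and quantile scaling, only the 6 libraries of a comparison, the replicate number as a block, eBayes without trend and robust, arrayWeights, an added minimum log2 change of 1, and leaving out each library in turn. Alternatives added after the data were seen were limma voom on the recovered reads, only the 129 genes above 0 in all 12 libraries, and leaving out the rRNA and mitochondrial genes. Other splits of the libraries were refitted, all 10 for 3 libraries against 3 and 100 drawn from 200 relabellings of genotype within age. The procedure was tested on simulated data in which 40 of 400 genes were changed. At 4 mpf 17.5% of 4-fold and 70% of 16-fold changes were recovered with all 12 libraries, with 4 false calls among 11 and 2 among 30. At 12 mpf the shares were 0% and 90%, with 0 false calls, and with the 6 libraries of 12 mpf alone 90% and 97.5%, with 7 false calls among 43 and 1 among 40. The simulation was 1 draw of negative binomial counts with 1 dispersion per age (0.876 at 4 mpf and 0.136 at 12 mpf), equal for both genotypes. With the 6 libraries of 4 mpf it kept 399 and 398 genes after the filter, against 356 in the data. It therefore held fewer values near 0 at that age.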

Results

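Gene expression was measured in hearts of ATF3-transgenic zebrafish and wild-type siblings at 4 and 12 mpf, with 3 libraries in each of the 4 groups. The series set out to separate early from progressive effects of ATF3, a stress-induced transcription factor, in heart muscle. The transgene's own effect on atf3, and the level of myl7, the cardiac myosin light chain gene whose promoter drives it, were not analysed here. The results cover 400 genes.

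Reads counted to cytosolic rRNA and to the mitochondrial gene mt-nd6, which codes for a subunit of respiratory complex I, made up most of the recovered reads. Their proportions differed between the ages. Whether the reads counted to mt-nd6 came from that gene or from the opposite strand was not settled. At 4 mpf the rRNA genes held 87.7% ± 4.30 of the reads in wild-type and 87.9% ± 2.78 in transgenic hearts (SD, n = 3). At 12 mpf they held 30.3% ± 11.7 and 32.4% ± 1.34 (SD, n = 3). The mt-nd6 share was 6.38% ± 3.64 and 5.20% ± 1.46 at 4 mpf, and 47.6% ± 9.37 and 44.3% ± 2.83 at 12 mpf (SD, n = 3). Over both genotypes each of these shares differed between the ages by an exact permutation test (6 libraries against 6, p = 0.00217, Benjamini-Hochberg adjusted p = 0.0189). The reads in the 400 genes averaged 931719 and 715325 per library in wild-type and transgenic hearts at 4 mpf, and 211247 and 216437 at 12 mpf. Outside the rRNA and mitochondrial genes they averaged 39145, 39666, 38383 and 45686 in the same order.

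Many genes were listed at 0 in the 4 mpf libraries. The wild-type libraries at 4 mpf had 193, 134 and 46 such genes and the transgenic ones 64, 81 and 98. At 12 mpf the counts were 4, 3 and 9 in wild-type and 9, 5 and 5 in transgenic libraries. Each of the 400 genes was above 0 in at least 6 libraries, and how the genes with values were chosen is not given in the sources used here, so the zeros describe these genes only. The ages differed by an exact permutation test (p = 0.00217, adjusted p = 0.0189), and the genotypes at 4 mpf did not (p = 0.4, exact permutation test, where 0.1 is the smallest possible). Spearman correlations between replicates lay between 0.477 and 0.604 in wild-type and between 0.531 and 0.629 in transgenic hearts at 4 mpf. They lay between 0.801 and 0.834 and between 0.855 and 0.882 at 12 mpf.

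**Figure D1:**
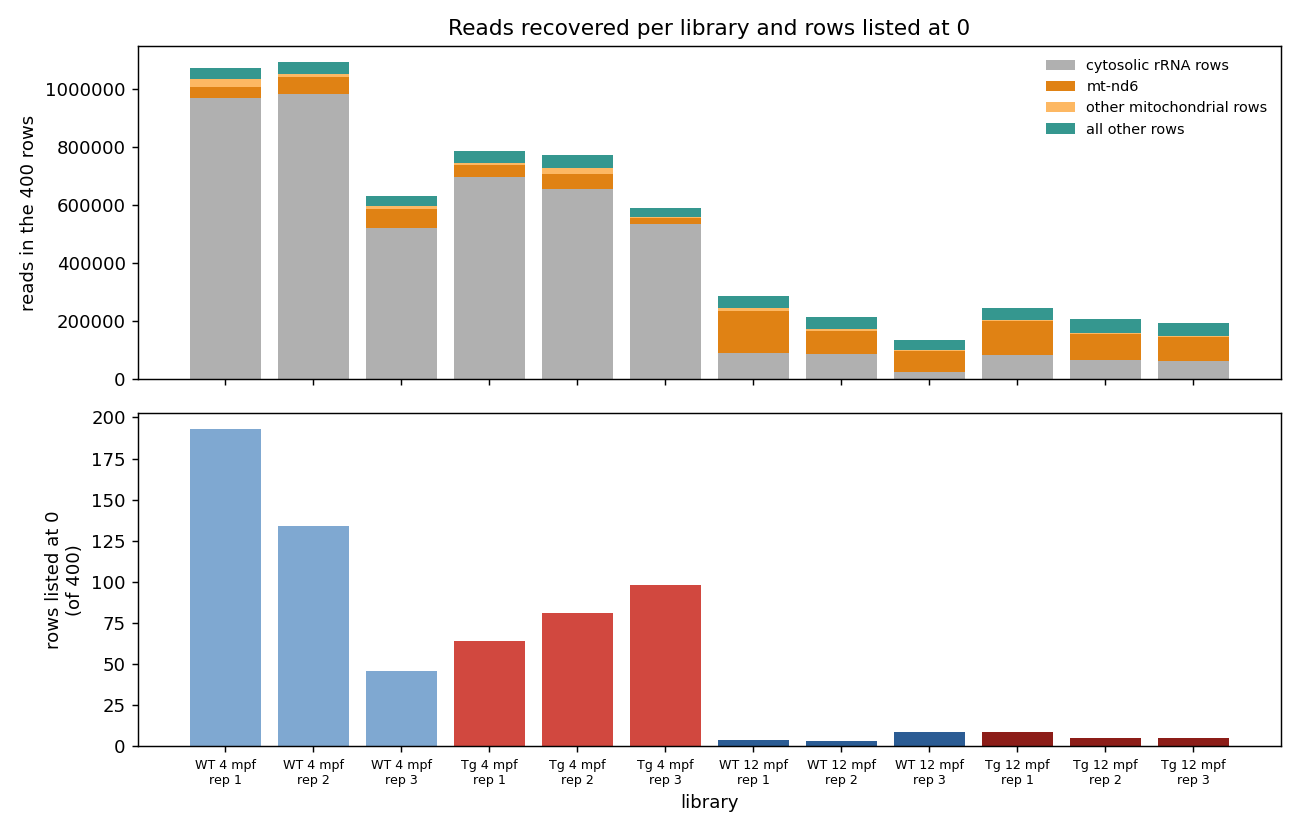
Reads recovered in the 400 genes of each library, by class (upper bars), and the number of the 400 genes listed at 0 (lower bars). The rRNA genes hold most reads in the 6 libraries of 4 mpf, and those libraries list 46 to 193 genes at 0 against 3 to 9 at 12 mpf.

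Most of the 400 genes lie opposite another gene. Of these genes, 68.0% overlapped a gene on the other strand, against 20.2% of the genes not analysed here (Fisher's exact test, p = 2.9e-93). The 3' end of an opposite gene lay inside or within 5000 bases of 87.5% of them, against 28.5% of the genes not analysed here (Fisher's exact test, p = 8.4e-133). Overlap with only the 5' end of an opposite gene inside was about as frequent in both, at 4.0% and 3.1% (Fisher's exact test, p = 0.31). The kit marks the strand, and the strand setting of the counting is not given in the sources used here. Reads of a named gene and of its opposite partner are therefore not separable. For named genes that passed, an overlapping partner is given where there is one. Among the mitochondrial protein genes mt-nd6, which alone lies on the minus strand, held a median of 91.24% of the reads over the 12 libraries. Symbols and gene functions below are labels of the listed gene. Which strand's transcripts gave the reads was not settled for single genes.

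**Figure D2:**
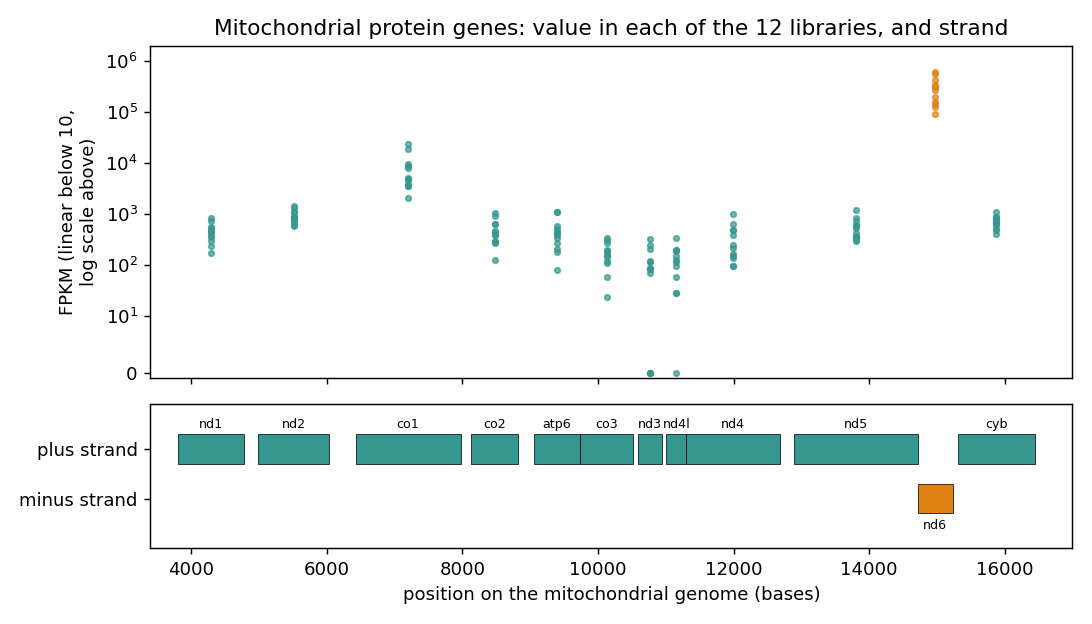
FPKM of each mitochondrial protein gene in each of the 12 libraries (points, log scale above 10 and linear below) above a map of the genes by strand and position in bases on the mitochondrial genome. The minus-strand gene mt-nd6 holds between 60.23% and 96.39% of the reads of these genes in a library.

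The first comparison addressed the early effect of the transgene. At 4 mpf 13 of the 400 genes differed between transgenic and wild-type hearts, 11 higher and 2 lower (limma, adjusted p under 0.05). As many came from 2 of the 10 splits of these libraries, the real one included. The B-cell surface protein gene cd22 was listed at 0 in all 3 wild-type libraries and at 91.0, 70.29 and 176.9 FPKM in the transgenic ones, at least 36.4-fold higher (limma, adjusted p = 0.00308). The heme synthesis enzyme alad showed the opposite pattern, at 19.9, 69.8 and 38.8 FPKM in wild-type libraries and listed at 0 in all 3 transgenic libraries, at least 18.7-fold lower (limma, adjusted p = 0.0101). All such bounds count each read as a separate molecule. If copying alone made the spread between libraries, it gave 33.88 reads per molecule in wild-type and 21.63 in transgenic libraries of 4 mpf. The genes at 0 gave 24.43 and 15.46. The bounds would then be lower by such factors. At the estimates from the spread, only the bound of cd22 (36.4 against 33.88) exceeds the reads per molecule of the group at 0. The other bounds at 4 mpf would then set no minimum change. The erythroid gene hemgn was listed at 0, 0 and 6.09 FPKM in wild-type and at 33.8, 20.5 and 45.8 FPKM in transgenic libraries (limma, adjusted p = 0.0285), a call lost in 15 of its 24 alternatives (adjusted p up to 0.4355).

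The CTP synthase gene ctps1a was listed at 0 in the 3 wild-type libraries and at 19.8, 12.4 and 9.90 FPKM in the transgenic ones, at least 16.96-fold higher (limma, adjusted p = 0.00308). The superoxide-producing NADPH oxidase gene nox1 was listed at 0 against 17.2, 24.4 and 10.6 FPKM, at least 9.49-fold higher (limma, adjusted p = 0.0101). The disulfide isomerase gene txndc5 was listed at 0 against 11.4, 25.0 and 8.84 FPKM, at least 8.55-fold higher (limma, adjusted p = 0.00920). The gene angel1 was listed at 0 against 9.30, 7.06 and 37.9 FPKM, at least 13.8-fold higher (limma, adjusted p = 0.0169). The scaffold protein gene mpp6a was listed at 0.569, 0 and 0 FPKM against 9.25, 11.01 and 22.8 FPKM (limma, adjusted p = 0.0158). The ADP-ribose hydrolase gene oard1, above 0 in all libraries, rose from 30.7 ± 8.64 to 141.8 ± 57.6 FPKM (SD, n = 3), a log2 change of 2.12 (SE 0.52, limma, adjusted p = 0.0471), a call lost in 16 of its 25 alternatives (adjusted p up to 0.4174). The calls of the other 7 named genes were lost in 2 to 4 of 24 alternatives each. All 7 were lost with the 6 libraries of 4 mpf alone and with arrayWeights, which each called 0 genes. Some alternatives could not change the calls: no filter and an added minimum log2 change of 1 returned the same 13 genes.

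**Figure D3:**
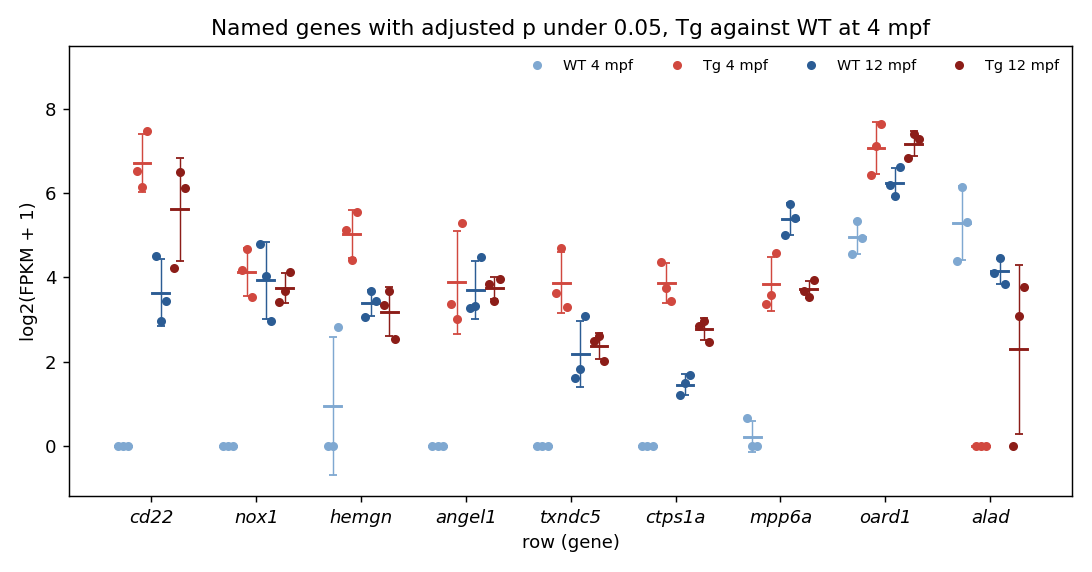
Expression as log2(FPKM + 1) of the 9 named genes that differed at 4 mpf, in each library of the 4 groups (points), with the group mean (bar) and SD (whisker, n = 3). The gene cd22 is at 0 in the 3 wild-type libraries of 4 mpf and alad in the 3 transgenic libraries of 4 mpf.

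Several of these genes had a partner on the other strand. The partner was trmo for hemgn, fam98b, spred1 and AL935141.1 for angel1, apobec2b for oard1 and clone-named genes for ctps1a. The nearest opposite 3' end lay 11 bases from nox1 (cstf2), 1136 from mpp6a (gsdmeb), 1798 from alad (tmem203) and 2264 from cd22 (ncam3), and none lay within 5000 bases of txndc5. On GRCz11 cd22 lies on chromosome 16 from 44906324 to 44917748, ctps1a on chromosome 19 from 16015881 to 16031503, alad on chromosome 5 from 54482325 to 54497319 and oard1 on chromosome 23 from 19220381 to 19225709. Groups did not overlap in any of the 13 genes, and in 48 of all 400 (12.0%), where chance gives 10%. Of the 11 rises, 10 were listed at 0 in at least 2 wild-type libraries, as were 110 of the 400 genes (27.5%). With the 6 libraries of 4 mpf alone limma called 0 genes (29 at an unadjusted p under 0.05), with arrayWeights 0 (30 unadjusted), with limma voom 21, and without wild-type replicate 3 of 4 mpf 37. Without wild-type replicate 1 of 4 mpf 8 genes were higher and 8 lower, so the surplus of rises was lost. In simulated data with 4-fold changes the fit to all 12 libraries made 4 false calls among 11 at 4 mpf, and with 16-fold changes 2 among 30. Those data held fewer values near 0 than the real ones and gave both genotypes 1 spread, so these rates may not hold here.

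Among the gene lists at 4 mpf, the erythrocyte list had 1 measured member, hemgn, which passed over all genes. The epithelial claudin gene cldni, the 1 measured member of the surface epithelium and gill list, had a log2 difference of 2.02 and did not pass (limma, adjusted p = 0.0752 over all genes). Its opposite partner was coro1a. Adjustment over a list of 1 gene leaves its p unchanged and was not counted as a pass. Members of the other lists with values did not pass over all genes or adjusted over the list alone. These were gmnn and racgap1 of the cell cycle, rpl4, rpl17, rpl31 and rpsa of the ribosome, psph of the integrated stress response, and stat1a of the interferon response. The others were itih2 of the liver list, ndufb2, ndufa3 and atp5f1e of oxidative phosphorylation, psma1 and psma6b of the proteasome, and the 12 mitochondrially encoded genes.

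The mitochondrially encoded genes, which code for subunits of the respiratory chain and ATP synthase, were lower as a group in transgenic hearts at 4 mpf by the preset test. Their median log2 difference was -0.68 against 0.27 for the other genes, and 0 of the 12 passed singly (limma's camera, adjusted p = 0.00216). With an estimated correlation the camera adjusted p was 0.113. At 12 mpf the median was -0.37 (camera, adjusted p = 0.00558), with an adjusted p of 0.147 under an estimated correlation. Over both ages it was -0.57 (camera, adjusted p = 0.000236), with an adjusted p of 0.0647 under an estimated correlation. At 12 mpf the preset call of limma's camera was lost without wild-type replicate 1 (adjusted p = 0.571) or transgenic replicate 3 of that age (adjusted p = 0.151). As small a p came from 6 of 10 splits of the libraries at 12 mpf and from 10 of 100 relabellings over both ages. The preset p at 12 mpf is therefore no evidence of a genotype effect, and chance is not excluded over both ages. At 4 mpf the real split gave the smallest camera p, with 0.00323 for the next. With 10 splits a share under 0.05 is not possible, so chance is not excluded there either. All members but mt-nd6 lie on the plus strand, and mt-nd6 held most of the mitochondrial protein reads. Whether the values are mRNA of the named genes was not settled.

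The comparison at 12 mpf addressed the later effect. By limma 0 of the 400 genes passed, with 13 at an unadjusted p under 0.05, and limma voom gave 0 with 9 unadjusted. Among genes with a proper symbol the smallest adjusted p was 0.852, for the palmitoyltransferase gene zdhhc13 on chromosome 7 from 16509201 to 16549089. It was at 33.7 ± 20.1 FPKM in wild-type and 163.9 ± 77.2 FPKM in transgenic hearts (SD, n = 3), a log2 difference of 2.38 (SE 0.67). Its opposite partner was csrp3, which codes for a muscle LIM protein. Of the next genes by unadjusted p, none of which passed (limma, adjusted p = 0.999 for each), the log2 difference was 0.78 for armc2 (partners BX842669.1 and sesn1), 2.75 for enpp5, 1.31 for ctps1a, 0.73 for cmbl (partner cct5) and 1.98 for cd22. It was -1.67 for mpp6a, -2.999 for grnas (partners grn1 and grn2), -4.17 for tma7 (partner dnase1l4.1) and -1.71 for rfx5 (partner BX927401.3).

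The count at 12 mpf differed between alternatives, and the cause of these changes was not tested. With the 6 libraries of 12 mpf alone limma called 1 gene, the lincRNA BX323041.1, chosen after its values were seen (adjusted p = 0.000480, against 0.852 or more in the fit to all 12 libraries), with 50 at an unadjusted p under 0.05. It was at 29.9, 90.6 and 62.4 FPKM in wild-type and listed at 0 in all 3 transgenic libraries of 12 mpf. Weighting the libraries with arrayWeights called 2 genes, zdhhc13 (limma, adjusted p = 0.0403, the lowest over its alternatives, which reached 1) and BX323041.1, with 54 unadjusted. Leaving out wild-type replicate 3 of 4 mpf called BX323041.1 alone. The groups did not overlap in 80 of the 400 genes (20%), where chance gives 10%. In simulated data the fit to all 12 libraries recovered 0% of 4-fold changes at 12 mpf, and the fit to the 6 libraries of that age recovered 90%, with 7 false calls among 43. None of the members of the 10 lists passed at 12 mpf over all genes or adjusted over the list alone.

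Over both ages 4 genes differed between the genotypes (limma, adjusted p under 0.05), 3 higher and 1 lower in transgenic hearts. As many came from 21 of 100 relabellings of genotype within age, the real one included. The gene ctps1a had a log2 difference of 2.58 (SE 0.40, 1.29 to 4.39 over its alternatives, limma, adjusted p = 0.00767), with 1.77 ± 0.449 FPKM in wild-type and 5.87 ± 1.18 FPKM in transgenic hearts at 12 mpf (SD, n = 3). The gene alad had a log2 difference of -3.57 (SE 0.69, -5.77 to -2.09 over its alternatives, limma, adjusted p = 0.0260, lost in 7 of 23 alternatives with adjusted p up to 0.1647), with 16.3, 21.0 and 13.5 FPKM in wild-type and 0, 7.48 and 12.7 FPKM in transgenic libraries at 12 mpf. The other 2, chosen after their values were seen, were cd22, with a log2 difference of 4.35 (3.07 to 6.05 over its alternatives), and the antisense gene BX072576.3, with 5.55 (3.99 to 7.77), which lies opposite mettl6 and rspo3. With arrayWeights cd22 and ctps1a passed, and without wild-type replicate 3 of 4 mpf 14 genes. Without wild-type replicate 1 of 4 mpf 4 genes were higher and 6 lower. The call of alad was lost with arrayWeights and without any 1 of the wild-type libraries of 12 mpf, transgenic replicates 1 and 2 of 4 mpf and transgenic replicate 2 of 12 mpf. Of the lists, 0 members passed over all genes.

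The genotype effect differed between the ages for 2 genes (interaction, limma, adjusted p under 0.05). As many came from 42 of 100 relabellings of genotype within age, the real one included. The scaffold gene mpp6a was higher in transgenic hearts at 4 mpf and did not pass at 12 mpf (limma, adjusted p = 0.999), where it was at 41.9 ± 10.8 FPKM in wild-type and 12.3 ± 1.89 FPKM in transgenic hearts (SD, n = 3). Its interaction was -5.29 on the log2 scale (SE 1.02, -7.89 to -3.26 over its alternatives, limma, adjusted p = 0.0482), a call lost in 14 of 23 alternatives (adjusted p up to 0.4958). The processed transcript CU695215.2, chosen after its values were seen, had an interaction of 7.42 (SE 1.40, 5.73 to 9.67 over its alternatives, limma, adjusted p = 0.0482), a call lost in 15 of 23 alternatives (adjusted p up to 0.2684). It was at 611.4, 164.3 and 193.0 FPKM in wild-type and 0, 0 and 10.5 FPKM in transgenic libraries at 4 mpf, and at 147.4 ± 77.0 and 195.2 ± 76.0 FPKM at 12 mpf (SD, n = 3). Median-of-ratios scaling called 0 genes (limma, 34 at an unadjusted p under 0.05), limma voom 1, and the fit without wild-type replicate 3 of 4 mpf 15. The mitochondrially encoded list did not differ (camera, adjusted p = 0.111, and adjusted p = 0.384 with an estimated correlation), and 0 members of the lists passed over all genes. Across the 400 genes the effects at the 2 ages had a Pearson r of 0.102 and a Spearman rho of 0.140, with 58.5% in the same direction.

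The change with age in wild-type hearts gives the background for the transgenic line. All libraries of 4 mpf differed from all those of 12 mpf in rRNA share and in genes at 0. An effect of age therefore cannot be told apart from a difference in library quality, in either genotype. From 4 to 12 mpf 12 genes rose and 4 fell (limma, adjusted p under 0.05). The gene mpp6a rose to 41.9 ± 10.8 FPKM (SD, n = 3, log2 change 5.17, SE 0.72, 2.91 to 7.77 over its alternatives, limma, adjusted p = 0.00253). The endosomal sorting gene chmp5b, listed at 0 in the 3 libraries of 4 mpf, was at 39.9, 17.1 and 54.0 FPKM at 12 mpf, at least 9.45-fold higher (limma, adjusted p = 0.0400). The rRNA methyltransferase gene ftsj3 rose from 0, 0 and 0.808 FPKM to 27.6 ± 5.08 FPKM (SD, n = 3, limma, adjusted p = 0.0400). The calls of chmp5b and ftsj3 were lost in 12 and 13 of 24 alternatives (adjusted p up to 0.1458 and 0.129). The genes nox1 and angel1 were listed at 0 at 4 mpf and were at least 8.865-fold and 10.01-fold higher at 12 mpf (limma, adjusted p = 0.0165 and 0.0204), calls lost in 5 and 7 of 24 alternatives (adjusted p up to 0.287 and 0.461). The bounds for chmp5b, nox1 and angel1 also count each read as a separate molecule. They would set no minimum change if reads were copies at the wild-type estimates for 4 mpf. The 4 falls, chosen after their values were seen, were the rRNA genes CT583728.7, CT583728.1 and CT583728.3 and the gene FO704772.3, with log2 changes of -3.12, -2.08, -2.77 and -3.91. The partner was CT583728.10 for CT583728.3 and FO704772.2 for FO704772.3.

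In wild-type hearts the median log2 change over the 400 genes was 1.03, against 0.124 over the 129 genes above 0 in all 12 libraries. Quantile scaling moved the first to -0.016 and called 2 rises and 3 falls. Of the 12 rises, 10 were listed at 0 in at least 2 wild-type libraries of 4 mpf, in which rRNA held 87.7% of the reads against 30.3% at 12 mpf. Groups did not overlap in 97 of the 400 genes (24.2%), where chance gives 10%. Without wild-type replicate 3 of 4 mpf 71 genes passed. The surplus of rises was lost without wild-type replicate 1 of 4 mpf (3 rises and 3 falls) and without wild-type replicates 1, 2 or 3 of 12 mpf (1 and 3, 2 and 3, and 3 and 4). The mitochondrially encoded list had a median of -0.11 and a mean of 0.18 against a median of 1.08 for other genes (camera, adjusted p = 0.0396, direction lower, and adjusted p = 0.268 with an estimated correlation). Of the other lists, 0 members passed over all genes.

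In transgenic hearts 8 genes rose and 6 fell from 4 to 12 mpf (limma, adjusted p under 0.05). Here too age and library quality cannot be told apart. The microtubule-associated gene map7d3 rose from 150.1 ± 43.3 to 587.1 ± 86.2 FPKM (SD, n = 3, log2 change 1.99, SE 0.47, limma, adjusted p = 0.0424), and the 3' end of the opposite gene fhl1a lies 12 bases from it. This call was lost in 12 of 25 alternatives (adjusted p up to 0.147). The value listed for the complex I gene mt-nd6 rose from 132258 to 409136 FPKM (log2 change 1.62, SE 0.40, limma, adjusted p = 0.0468). This call was lost in 16 of 24 alternatives (limma, adjusted p up to 0.1915). Reads of its opposite partner mt-nd5 are not separable from those of mt-nd6. The folate carrier gene slc19a1 fell from 180.7 ± 34.2 to 17.2 ± 14.98 FPKM (SD, n = 3, log2 change -3.62, SE 0.79, limma, adjusted p = 0.0319), beside its opposite partner LO018113.1, a call lost in 5 of 25 alternatives (adjusted p up to 0.1281). The rRNA genes CT583728.7, CT583728.3 and CT583728.1, chosen after their values were seen, fell by 2.25, 2.74 and 1.57 on the log2 scale, calls lost in 6, 5 and 10 of 24 alternatives (limma, adjusted p up to 0.1279, 0.1222 and 0.1885).

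In transgenic hearts the median log2 change over the 400 genes was 0.64, against 0.0701 over the 129 genes above 0 in all 12 libraries. Median-of-ratios scaling moved the first to 0.54 and quantile scaling to -0.052. Quantile scaling called 12 rises and 16 falls, and without transgenic replicate 3 of 12 mpf limma called 0 genes (47 at an unadjusted p under 0.05). Groups did not overlap in 134 of the 400 genes (33.5%), where chance gives 10%. Of the mitochondrially encoded list mt-nd6 alone passed, over all genes and adjusted over the list alone, and the list did not differ from other genes (camera, adjusted p = 0.703, and adjusted p = 0.831 with an estimated correlation). Of the ribosomal list 3 of 4 members and of the proteasome list 1 of 2 passed adjusted over the list alone, and 0 passed over all genes.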

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

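The depth test and the relabellings of genotype were chosen only after the results were seen.

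The transgene effect differed between the ages for mpp6a, by -5.29 on the log2 scale (12 mpf minus 4 mpf, limma interaction, adjusted p = 0.0482). In 14 of its 23 other settings the adjusted p was above 0.05, over a range of 0.0118 to 0.496, while the direction was the same in all 23. It also differed for CU695215.2, by 7.42 (adjusted p = 0.0482, above 0.05 in 15 of its 23 other settings over a range of 0.002815 to 0.2684), whose values rest on 73, 19 and 19 reads in wild-type and 0, 0 and 1 reads in transgenic libraries of 4 mpf. With the interaction called in 2 genes, 42 of 100 relabellings of genotype within age called as many, and the highest other count was 14, so chance is not excluded for the count. Whether a relabelling that called several times as many reflects noise or a structure among the samples other than genotype was not tested.

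Both genes were at 0 in 2 libraries of a 4 mpf group, and such zeros were common at that age. Thinning the 12 mpf profile to the reads of each 4 mpf library gave a mean of 0.25 genes at 0, against 101 ± 52.4 seen over the 6 libraries (SD, 380 genes outside rRNA and mitochondrion). Reads in these genes averaged 39145 and 39666 in wild-type and transgenic libraries of 4 mpf, against 38383 and 45686 at 12 mpf. The zeros thus did not go with fewer reads in these genes. With reads so alike the thinning could give few zeros, and it does not test the depth of the whole library. Many copies of few starting molecules stays open as a candidate explanation. Reads per molecule estimated from the variance (21.63) and from the zeros (15.46) in transgenic libraries of 4 mpf lay within a ratio of 1.4. They were 33.88 and 24.43 in wild-type libraries of 4 mpf. At 12 mpf they were 3.74 and 2.62 in transgenic and 4.78 and 2.74 in wild-type libraries. The variance counts any spread between libraries as copies, and the estimates lay close in every group, so their closeness cannot decide. A choice of the 400 genes that favoured those above 0 at 12 mpf, and a biological effect of the transgene or of age, also stay open, untested.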

How the results depend on the processing

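Limma voom, the restriction to genes above 0 in all 12 libraries, and the omission of rRNA and mitochondrial genes were chosen after the data were seen. For the 30 results of single named genes, 576 of 722 alternative results kept their direction and their side of the threshold. Of the others, 145 lost the threshold, 1 gained it and 0 changed direction. The 30 include the genes named between genotypes at 12 mpf, which had not passed and so could not lose the threshold. Their alternatives count among the 576 by staying above 0.05. All 145 losses came from results that had passed, so the pooled share overstates how often a call held. Between genotypes at 4 mpf, 13 genes became 6 with quantile scaling (4 higher and 2 lower), 0 with the 6 libraries alone, 0 with arrayWeights, 21 with voom and 6 with genes above 0 throughout (1 shared). At 12 mpf, 0 became 1 with 6 libraries and 2 with arrayWeights. Over both ages, 4 became 8 with a pseudocount of 0.1, 2 with arrayWeights and 2 with genes above 0 throughout (0 shared). For the interaction, 2 became 0 with a pseudocount of 0.1, 1 with 5, 0 with median-of-ratios scaling, 1 without trend and robust, 1 with voom and 0 with genes above 0 throughout. With age in wild-type hearts, 16 became 9 with a pseudocount of 5, 5 with quantile scaling, 28 with 6 libraries, 1 with arrayWeights, 49 with voom and 8 with genes above 0 throughout. In transgenic hearts, 14 became 28 with quantile scaling (12 higher and 16 lower), 2 without trend and robust, 22 with voom and 6 without rRNA and mitochondrial genes. The 129 genes above 0 throughout are fewer genes tested, and the cause of the other changes was not tested.

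Replicate numbers did not pair the libraries, since correlations of same-numbered deviations ran from -0.411 to 0.0761. The replicate block gave 0 genes for the interaction and 6 with age in transgenic hearts, against 2 and 14, and moved no other count by over 1.5 times.

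Leaving out 1 library gave 9 to 37 genes at 4 mpf, 0 to 1 at 12 mpf, 3 to 14 over both ages, 0 to 15 for the interaction, 4 to 71 with age in wild-type and 0 to 24 in transgenic hearts. The highest counts came without wild-type replicate 3 of 4 mpf, except the last, which came without wild-type replicate 1 of 4 mpf. Over both ages 10, 9 and 10 genes passed without replicates 1 and 2 of wild-type and 3 of transgenic hearts of 4 mpf. For the interaction 0 passed without wild-type replicate 2 or transgenic replicate 1 of 4 mpf or any library of 12 mpf, and 1 without transgenic replicate 3 of 4 mpf. With age in wild-type hearts 6 passed without wild-type replicate 1 and 28 without transgenic replicate 3 of 4 mpf, and 4, 5 and 7 without wild-type replicates 1, 2 and 3 of 12 mpf. With age in transgenic hearts 8 and 9 passed without wild-type replicates 2 and 3 of 12 mpf, 7 and 2 without transgenic replicates 2 and 3 of 4 mpf, and 2 and 0 without transgenic replicates 2 and 3 of 12 mpf.

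For the mitochondrially encoded list, camera p at 4 mpf was 0.0779 with quantile scaling and 0.113 with an estimated correlation, which gave 0.147 at 12 mpf, 0.0647 over both ages and 0.268 with age in wild-type hearts. The last comparison also lost its call with a pseudocount of 5 (0.0835), arrayWeights (0.114) and genes above 0 throughout (0.551), and turned upward with quantile scaling (0.579). With age in transgenic hearts, not called, the direction turned with quantile scaling (0.491), genes above 0 throughout (0.871), and without transgenic replicate 2 of 4 mpf (0.661) or 3 of 12 mpf (0.807). Leaving out 1 library gave p of 0.000307 to 0.0329 at 4 mpf, 0.000157 to 0.571 at 12 mpf, 2.774e-05 to 0.00553 over both ages, 0.00753 to 0.398 for the interaction, 0.00159 to 0.219 with age in wild-type and 0.425 to 0.807 in transgenic hearts. The interaction passed without wild-type replicate 1 of 12 mpf (0.00753), transgenic replicate 2 of 4 mpf (0.0235) or 3 of 12 mpf (0.0319). Age in wild-type did not pass without replicate 1 of 4 mpf (0.219) or 2 and 3 of 12 mpf (0.124 and 0.173). The correlation of effects was 0.271 with genes above 0 throughout, and 0.0481 to 0.134 with 1 library left out.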

Other observations

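The tests of the mt-nd6 share, of the shared spread and of other splits were chosen only after the results were seen. The genes of the next paragraph were picked because they lie opposite a list gene, after their values were seen.

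Of the lists of the cardiac sarcomere and of cardiac stress and hypertrophy, lmod2a, tnnc1a, acta1b, csrp3 and fhl1a lay opposite a gene with values or close to one. The gene CR762497.1, opposite the actin gene acta1b, was at 928 ± 283 FPKM in transgenic hearts at 4 mpf and 5826 ± 815 FPKM at 12 mpf (SD, n = 3), a log2 change of 2.68 (limma, adjusted p = 0.0190). In wild-type hearts the change was 1.01 (limma, adjusted p = 0.235), and the difference between the genotypes did not pass (limma interaction, adjusted p = 0.515). Between genotypes none of the 5 passed at either age, and the differences went in both directions. At 4 mpf the log2 differences were -1.84 for CR762497.1, -2.93 for wasla (opposite lmod2a), -1.28 for atp6ap1a (tnnc1a), 0.70 for zdhhc13 (csrp3) and -0.41 for map7d3 (fhl1a) (limma, adjusted p of 0.0710 to 0.7155). At 12 mpf they were -0.17, -0.82, 0.98, 2.38 and 0.35 in the same order (limma, adjusted p of 0.852 to 0.999). Of other lists, a gene opposite the glycolytic enzyme gene pkma rose with age in transgenic hearts by 1.57 on the log2 scale (limma, adjusted p = 0.0297). Its change in wild-type hearts was 1.25 (limma, adjusted p = 0.0513), and the difference did not pass (limma interaction, adjusted p = 0.918).

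A hypothesis is that the counts were taken on the strand opposite to that of the kit, so that many values may be reads of the partner. The minus-strand gene mt-nd6 held a median of 91.24% of the mitochondrial protein reads, where the prediction for that cause was over 50% and otherwise under 1 in 12. Its share was at least 60.23% in every library, which argues against counts on the kit's strand for the mitochondrial protein genes. Among protein-coding genes that overlap an opposite gene, those with values held an opposite 3' end in 92.02% of 213, against 58.4% of 4644 others, a difference of 33.62 percentage points, which is in line with 3' reads of the partner. Both tests leave open how the 400 genes came to hold values, and no biological explanation was tested. Of the 20 genes with the highest values outside rRNA and mitochondrion, 16 had an opposite 3' end inside or within 5000 bases. Under this hypothesis the symbols in the results could name the partner's strand and not the expressed gene, also where genes lie close without overlap.

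The 13 genes called at 4 mpf may depend on a spread shared with the less variable libraries of 12 mpf. The median SD on the log2 scale was 2.03 and 1.27 in wild-type and transgenic libraries of 4 mpf, against 0.558 and 0.465 at 12 mpf. With the 6 libraries of 4 mpf alone 0 genes passed. In simulated data that fit called 17 genes with 16-fold changes and 0 with 4-fold changes, against 30 and 11 with all 12 libraries, and the number of libraries and the shared spread were not separated. The simulated data held fewer values near 0 than the real libraries of 4 mpf. An effect of the transgene stays open.

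With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split called 13 genes between genotypes at 4 mpf and the highest other 13, at 12 mpf 0 and 1, with age in wild-type hearts 16 and 1, and with age in transgenic hearts 14 and 0. As large a count came from 2 of the 10 splits at 4 mpf, 10 at 12 mpf and 1 in each age comparison. For the mitochondrially encoded list the camera p was 0.00216 for the real split and 0.00323 for the next at 4 mpf, with 1 of 10 as small. It was 0.00558 and 4.515e-07 at 12 mpf (6 of 10), 0.0396 and 0.000175 with age in wild-type (3 of 10), and 0.703 and 0.00562 with age in transgenic hearts (8 of 10).

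Among 100 relabellings of genotype within age, chance is not excluded for the results over both ages. As many as 4 genes came from 21, with up to 11 genes. The highest of many relabellings can exceed the real count through noise, and a structure among the samples was not tested. A list p as small as 0.000236 came from 10, the smallest being 4.655e-06, and for the list's interaction 0.111 came from 43, the smallest being 6.668e-06. A correlation as large as 0.102 between the effects at both ages came from 13, with up to 0.151.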
